A study of Mus musculus with 14 samples.

How the data were processed

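The series holds 14 SMART-Seq2 libraries of sorted mouse retinal microglia, 1 library per retina, from wild-type C57BL/6 mice aged 12 weeks. Per the labels a retina yielded 100 to 600 sorted cells, lysed at 100 to 300 cells in 5 µl of buffer. Groups were taken from the labels: microbead (3 libraries), contralateral (3), sham (4) and naive (4). Replicate numbers were taken as labels only, since no label says that they mark a shared mouse.

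Each library has its own table with expected counts, that is estimated reads per gene, which the authors neither scaled to depth nor to length per the file headers. The same tables give FPKM, which the authors scaled to effective length in kilobases and to the number of mapped reads. A series-wide table by the authors gives FPKM for the 14 libraries, and its values differed from those of the single tables by more than 0.006 in 0 cases. It names 47273 of the 47729 gene identifiers. Of the 456 identifiers it leaves out, 1 ribosomal RNA gene held 5.22 to 24.2% of the reads of each library. The labels name Salmon 1.4.0, R 4.0.3, DESeq2 1.30.1 and the build mm10, without their roles. The column names are those of RSEM, and the tool that wrote the tables is not given in the sources used here. Symbols came from the authors' table for 47247 identifiers and from a reference table for 85, while 397 had no symbol, and 47310 matched GENCODE M21, from which the coordinates were taken.

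Expected counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups and a minimum count of 10, which left 14279. Library sizes were scaled by TMM factors. One quasi-likelihood model (glmQLFit, robust) with 1 coefficient per group and no covariate was fitted to all 14 libraries, with 10 residual degrees of freedom and a common biological coefficient of variation of 1.13. Each of the 6 pairs of groups and the joint difference among the 4 groups were tested with glmQLFTest, two-sided, and p values were adjusted by Benjamini-Hochberg over all genes tested with a threshold of 0.05. Standard errors are the log2 fold change divided by the root of its F statistic. Levels are CPM with TMM scaling, given as mean ± SD over libraries. Where a group had 0 reads of a gene, the fold is a lower bound from a floor of 3 reads over that group.

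Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and adjusted over the lists of a comparison. Camera asks whether the genes of a list differ more than other genes do. Of 28 lists fixed, 21 had the minimum of 5 measured members and were tested. The 7 lists with fewer were bipolar cell, amacrine and horizontal cell, retinal ganglion cell, retinal pigment epithelium and lens, neutrophil, lymphocyte and erythrocyte, so these cells were not detectable as lists at this depth. The MGnD list comes from general knowledge of microglia, and Apoe belongs to it and to the lists of lipid handling and of Muller glia and astrocytes. List medians were also computed with genes at 0 reads in a group set to their bound, which changed 3 of 147.

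The genes named in the text follow a rule. For each comparison they are up to 12 of the largest rises and 12 of the largest falls among genes past the threshold with a mean of at least 10 CPM and groups that do not overlap, predicted genes and pseudogenes left out. Where fewer than 10 genes pass, the 6 genes with the smallest p are added, together with up to 4 genes with the smallest p from each list. The sort markers and a panel of state genes are given for every microbead comparison. Groups, lists, tests, the rule and most alternatives were fixed before the data were examined.

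Alternatives fixed with them were the size factors of DESeq2, no filter, a filter of at least 50 reads, the Wald test of DESeq2 1.42.0, limma voom with quality weights, the compared groups alone, the replicate number as a block, the mean of the rod genes as a covariate, leaving out each library, camera with an estimated correlation, and fry, which asks whether the genes of a list move on balance in a direction. After the data had been seen, 4 things were added: leaving out identifiers absent from the authors' table, leaving out libraries with fewer than 12000 genes, a comparison of microbead with the mean of sham and naive, and removal of a length trend. For the last, a lowess curve (span 0.5) of log2 CPM on transcript length was fitted in each library over genes of at least 10 CPM and removed through offsets.

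The procedure was tested on simulated data for microbead against naive, with 200 changed genes in each of 10 runs. Each gene was drawn with the spread estimated from its counts, the same in all libraries. A spread that differs between groups was not simulated, so the share of false calls below does not cover it. It recovered 0.2% of genes raised 2-fold, 10.2% of those raised 4-fold, 12.6% of those lowered 8-fold and 21.4% of those lowered 16-fold. Of its calls, 2.2% were false. No rise above 4-fold and no fall below 8-fold was simulated, so these shares do not separate the size of a change from its direction. Most of the changes put in went undetected at this depth and number of libraries. Camera called 0 of 206 unchanged lists and a list shifted 2-fold in 9 of 10 runs. The simulated genes were drawn independently, so these runs do not test camera where genes of a list vary together. Among other splits of the real libraries, camera called up to 12 lists against sham and 13 against naive. With a simulated length trend it called the ribosomal list in 10 of 10 runs as counted and in 0 of 10 with the trend removed. The trend put in and the trend removed came from the same kind of curve. No true rise of the ribosomal list was simulated, so these runs cannot show whether the removal also erases real changes of short genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.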

Results

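Gene expression was measured by SMART-Seq2, a full-length cDNA method for small numbers of cells, in microglia sorted from mouse retinas. Microglia are the resident macrophages of the retina, and they were sorted as CD11b-positive, Ly6c-negative, Fcrls-positive cells from wild-type C57BL/6 mice aged 12 weeks. Each of the 14 libraries came from 1 retina. The libraries formed 4 groups: 3 retinas injected with microbeads (microbead), 3 retinas contralateral to a microbead injection (contralateral), 4 retinas with a sham injection (sham) and 4 uninjected retinas (naive). The labels describe the microbead retinas as glaucoma, a disease in which retinal ganglion cells die, and the title of the series names MGnD, a neurodegeneration-associated state of microglia. No measurement of eye pressure or of nerve damage was used here.

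Total counts assigned to genes ran from 1.34 to 14 M reads per library, with a median of 11.5 M. The microbead libraries held 1.34, 10.7 and 13.9 M reads, and the contralateral libraries 6.03, 7.60 and 14 M. Group means were 8.64 M ± 6.52 (SD, n = 3) for microbead, 9.21 ± 4.22 (n = 3) for contralateral, 11.9 ± 2.28 (n = 4) for sham and 10.6 ± 2.40 (n = 4) for naive. Microbead 1 and contralateral 2 had reads in 10167 and 10306 genes, fewer than 12000, whereas no other library had fewer than 12000. These 2 libraries also had the lowest mean Spearman correlation with the other libraries, 0.665 for microbead 1 and 0.649 for contralateral 2, against 0.743 to 0.819 elsewhere.

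The markers used for the sort were read in all groups. Itgam, which encodes CD11b, averaged 376 CPM (counts scaled to library size) ± 81.2 in microbead, 445 ± 126 in contralateral, 427 ± 88.2 in sham and 337 ± 41.9 in naive libraries (mean ± SD). Fcrls averaged 725 ± 267, 511 ± 238, 625 ± 164 and 704 ± 210.0 CPM in the same order. Ly6c2, a gene for the Ly6c antigen used to exclude monocytes, had 0 reads in every library. Reads are PCR copies without molecular identifiers, so the floors used for groups without reads of a gene cover counting error only. The SDs and edgeR's standard errors given here rest on the spread between libraries.

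Transcript length separated the microbead libraries from the rest. For each library, each gene's log2 CPM was taken relative to the naive mean, and the median over genes of more than 4000 bases was subtracted from that over genes of at most 1000 bases. This difference was 1.75, 0.84 and 1.25 in the microbead libraries. The contralateral libraries stood at 0.40, 0.73 and -0.23, the sham libraries between -0.06 and 0.16, and the naive libraries between -0.27 and 0.16. Accordingly, the 760 short genes had a median log2 fold change of 0.90 in microbead against sham, and the 1114 long genes had one of -0.21. Values with this length trend removed from each library, a comparison chosen after the data had been seen, are given below beside gene groups that it moves. They are not given for lists that camera did not call as counted, and fry was not run with the trend removed.

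**Figure D1:**
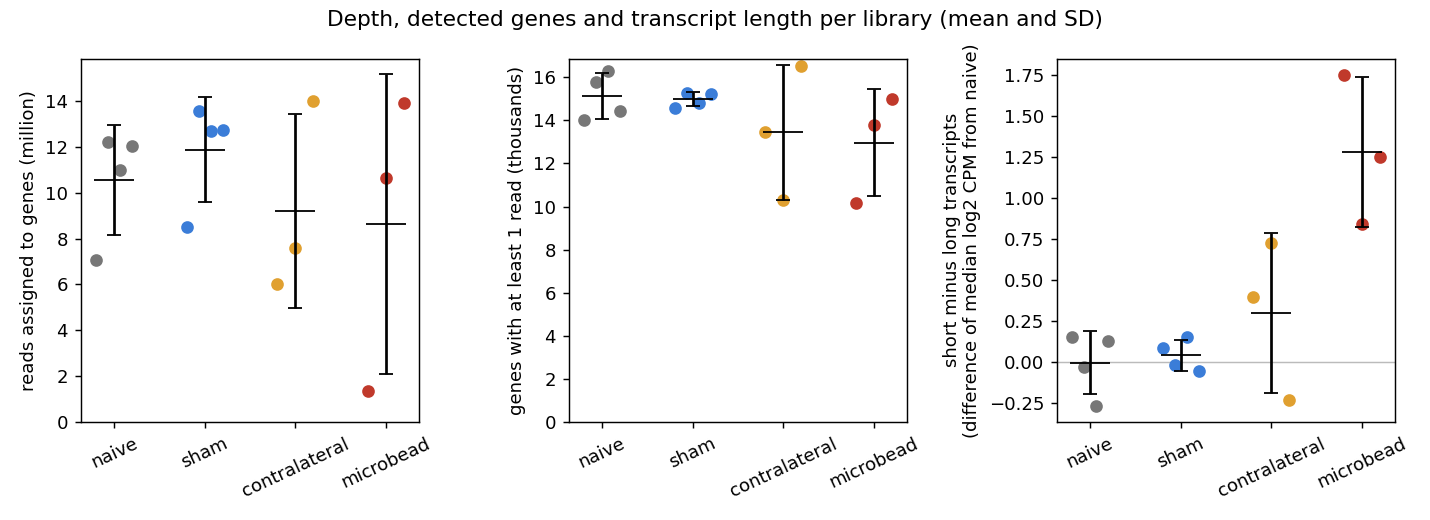
Reads assigned to genes (M), genes with at least 1 read and the log2 level of short minus long transcripts in each of the 14 libraries, by group; points are libraries, and lines with bars are the group mean and SD. The 3 microbead libraries lie between 0.84 and 1.75 for short minus long transcripts, above all other libraries, the highest of which is 0.73.

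Microbead retinas were compared with sham-injected retinas to ask how microglia differ after microbeads rather than after an injection alone. Apoe, which encodes the lipid carrier apolipoprotein E and is a hallmark of the MGnD state, rose 7.63-fold in microglia of microbead retinas, from 4262 ± 1168 (n = 4) to 32510 ± 18400 CPM (n = 3). Cd72, a C-type lectin co-receptor, rose 5.86-fold, from 71.4 ± 13.2 to 418 ± 214 CPM. Genes of the MGnD list, of antigen presentation, of the interferon response and of complement also stood higher as groups in camera. Each of these calls was lost with an estimated correlation (adjusted p = 0.0586, 0.174, 0.371 and 0.174). The list of the homeostatic program did not pass camera but was lower by fry (adjusted p = 0.0221). Of its genes, Cx3cr1 had a log2 fold change of -1.01 (SE 0.22, adjusted p = 0.0745) and P2ry12 one of -1.60 (SE 0.44, adjusted p = 0.168), neither of which passed the test.

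Of 14279 genes, 2 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with the Benjamini-Hochberg correction, both higher in microbead, while 1392 had an unadjusted p under 0.05. Apoe (ENSMUSG00000002985.16, chromosome 7, 19696109 to 19699188, minus strand) had a log2 fold change of 2.93 (SE 0.44, adjusted p = 0.0366). Cd72 (ENSMUSG00000028459.11, chromosome 4, 43446462 to 43454628, minus strand) had one of 2.55 (SE 0.41, adjusted p = 0.0429). For both genes every microbead library lay above every sham library. Complement component C4b was next among genes of the lists that did not pass, at 776 ± 275 CPM against 43.2 ± 37.4, with a log2 fold change of 4.17 (SE 0.78, adjusted p = 0.0664). The lysosomal thiol reductase Ifi30 (log2 fold change 1.98, SE 0.37) and the interferon-induced Ifi27l2a (3.05, SE 0.59) shared that adjusted p of 0.0664. The median log2 fold change of all genes was -0.12 here, -0.14 against naive and -0.08 against contralateral.

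Of the 31 measured genes of the MGnD list, 26 were higher in microbead, the median log2 fold change was 0.90, and the list passed limma's camera test (adjusted p = 6.5e-08; adjusted p = 0.0586 with an estimated correlation). Adjusted over the list alone, 9 of its genes rose, among them Apoe, the tetraspanin Cd63 (log2 fold change 1.46), the ferritin chain Fth1 (1.11) and the surface antigen Cd52 (1.85), against 1 gene over all genes tested. Gpnmb, a glycoprotein of lipid-laden phagocytes, also passed over the list alone and spread widely, at 14.4, 105.6 and 516 CPM in the 3 microbead libraries against a sham mean of 0.32. Spp1, which encodes osteopontin, was at least 351-fold higher than in sham, where it had 0 reads (floor of 3 reads over the group), but all of its microbead reads came from microbead 2, at 62.7 CPM. Other members of the state did not pass: Clec7a had a log2 fold change of -0.48 (SE 0.64), Axl one of 0.15 (SE 0.41), Itgax one of 0.55 (SE 1.07), Lpl one of 0.19 (SE 1.01) and Trem2 one of 0.25 (SE 0.23). Igf1 had one of 3.10 (SE 2.71), Csf1 one of 0.86 (SE 1.43), Lgals3 one of 3.75 (SE 1.91) and Cst7 one of 2.65 (SE 1.17). With the length trend removed the MGnD median was 0.64, and the list still passed (adjusted p = 0.00679).

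Antigen presentation genes had a median log2 fold change of 0.80 (camera adjusted p = 4.6e-04; adjusted p = 0.174 with an estimated correlation), and 3 of 20 rose adjusted over the list alone: H2-Q7, the MHC light chain B2m (0.88) and H2-D1. Interferon response genes had a median of 0.58 (adjusted p = 0.00340; adjusted p = 0.371 with an estimated correlation), with Ifi27l2a and Ifitm3 (1.99) as the 2 of 28 that rose over the list alone. The median of inflammatory cytokines and NF-kB targets was 0.72 (adjusted p = 0.00239; adjusted p = 0.174 with an estimated correlation), and the chemokine Ccl12 (2.40, SE 0.54) was the 1 of 22 that rose over the list alone. Complement genes had a median of 0.38 (adjusted p = 0.00375; adjusted p = 0.174 with an estimated correlation), with C4b and C1qb (0.68) as the 2 of 15. Phagocytosis and lysosome genes had one of 0.21 (adjusted p = 0.00340; adjusted p = 0.341 with an estimated correlation), with 6 of 33, among them the Fc receptor genes Fcer1g (1.63) and Fcgr1 (1.13) and the protease Ctsh (0.83). The length-corrected medians of these 5 lists, in the same order, were 0.45, 0.47, 0.38, 0.19 and 0.18, and the inflammatory list no longer passed (adjusted p = 0.189). In the homeostatic list, which did not pass camera (median -0.48, adjusted p = 0.0562), 8 of 28 genes fell adjusted over the list alone, including the fractalkine receptor Cx3cr1, the purinergic receptor P2ry12, the colony-stimulating factor receptor Csf1r (-0.82) and Tgfbr1 (-0.77), and 1, Ltc4s, rose. Tmem119 and the transcription factor Sall1 had log2 fold changes of -0.63 (SE 0.24) and -0.45 (SE 0.36).

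Cytosolic ribosomal protein genes had a median log2 fold change of 1.52 (camera adjusted p = 1.4e-29; adjusted p = 0.102 with an estimated correlation), and 38 of 39 rose adjusted over the list alone. Oxidative phosphorylation genes had one of 1.18 (adjusted p = 6.5e-08; adjusted p = 0.0120 with an estimated correlation), with 11 of 30 rising, Cox8a and Cox4i1 among them, and Sdha falling. Transcripts of the mitochondrial genome had one of 0.92 (adjusted p = 4.6e-04; adjusted p = 0.341 with an estimated correlation), with 0 of 13 passing edgeR's test over the list alone, where mt-Co2, mt-Nd6, mt-Nd4l and mt-Atp6 had an unadjusted p under 0.05. Removal of the length trend brought these 3 medians to 0.23, -0.11 and 0.02, and camera gave all 3 lists a downward direction. The oxidative phosphorylation list then passed as lower (adjusted p = 0.00679). Many ribosomal protein genes have near-identical pseudogenes, so the assignment of their reads is uncertain. Among markers of other cells, infiltrating monocyte and macrophage genes had a median of 1.71 (adjusted p = 0.0509), rod photoreceptor genes 0.75 (0.118), cone genes 0.00 with a mean of -0.17 and an upward direction (0.352) and border-associated macrophage genes -2.04 (0.0644). Muller glia and astrocyte genes had a median of 0.01 with a mean of -0.64 and an upward camera direction (adjusted p = 0.312), and endothelial and pericyte genes a median of 1.28 with a mean of -0.15 (0.675). Genes of TGF-beta signalling (median -0.25, 0.413), proliferation (-0.43, 0.259) and glycolysis (0.32, 0.259) did not pass camera as lists, while fry called TGF-beta signalling lower (adjusted p = 0.0430). Neither did lipid handling (median -0.01 and mean -0.04 with an upward camera direction, adjusted p = 0.306) nor the immediate early and heat shock genes that respond to cell isolation (-0.07, upward, 0.868).

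The calls of Apoe and Cd72 against sham rested on the number of sham libraries: without sham 1, 2, 3 or 4 in turn, 0 genes passed edgeR's test. The count was 18 without microbead 2, 134 without microbead 3, and 0 with the length trend removed, where the log2 fold change of Apoe was 2.497. By mean log2 CPM per library, every microbead library lay above every sham library for the MGnD, ribosomal, oxidative phosphorylation and mitochondrial lists, while the groups overlapped for the other 5. Relative to the naive mean, microbead 1 scored -0.0556 on the lysosome list, below all sham libraries (0.1222 to 0.394). On the interferon list it scored -0.1658, below sham 2, 3 and 4. A given library also decided 3 list calls: interferon (adjusted p = 0.154 without microbead 2), complement (0.0548 without microbead 3) and lysosome (0.0715 without microbead 3). Over all alternatives the lowest adjusted p of the 9 lists lay between 2.1e-44 and 0.00205, and the highest between 0.0120 for oxidative phosphorylation and 0.617 for the interferon response. For oxidative phosphorylation this range includes the opposite call with the length trend removed.

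**Figure D2:**
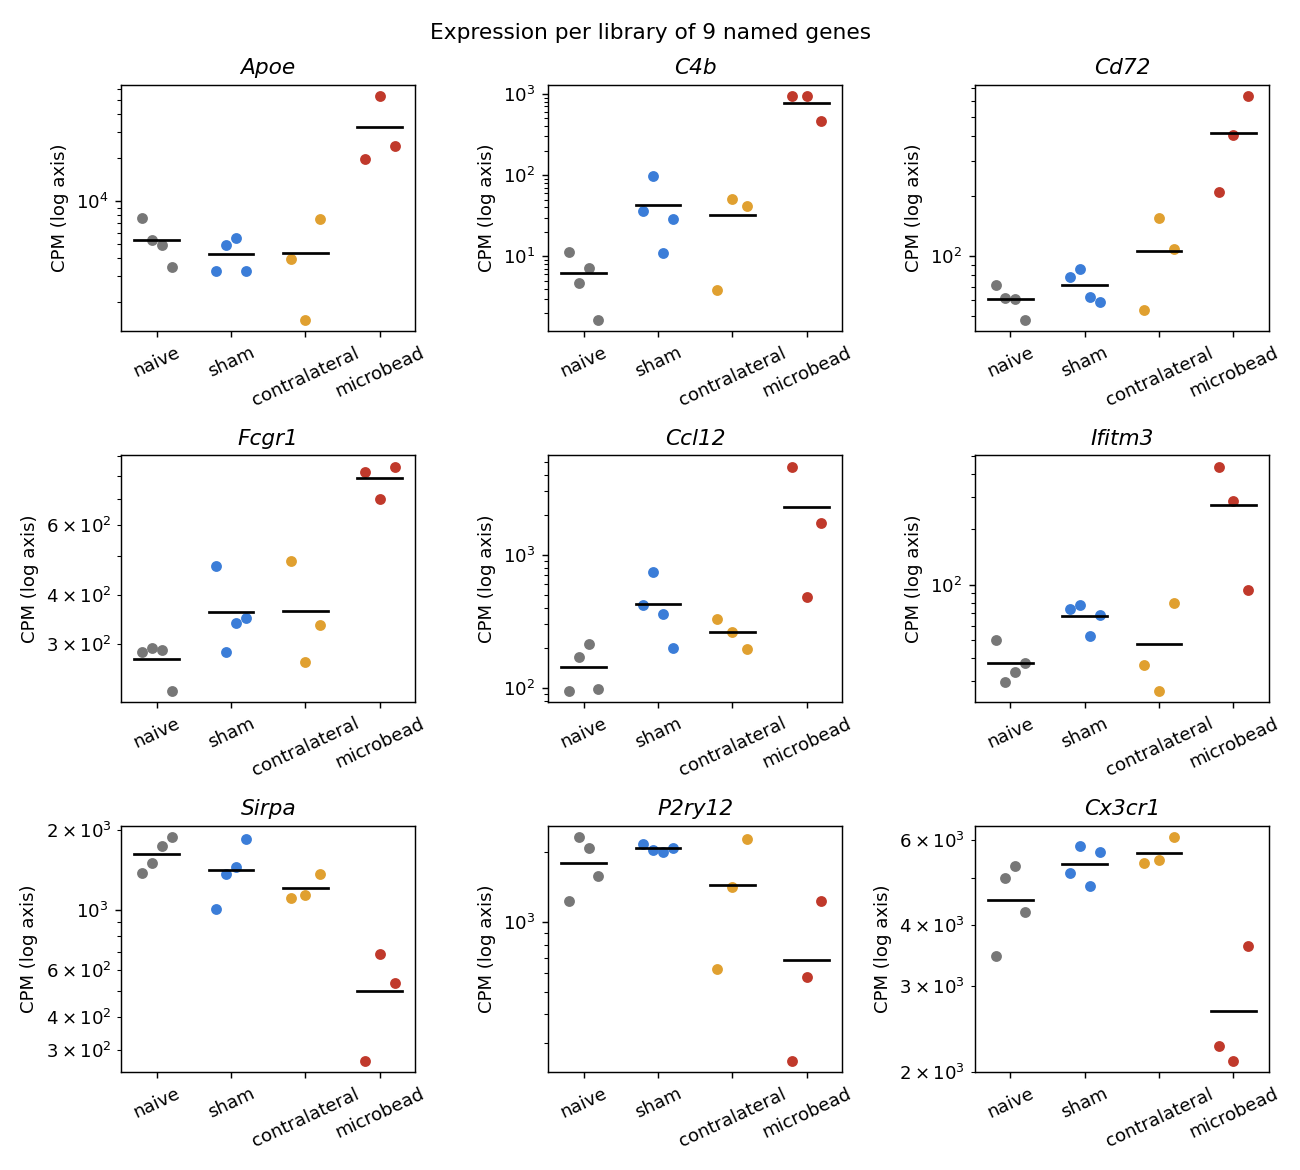
CPM (log axis) of 9 genes in each library, by group; points are libraries and lines are group means. Apoe lies at 19620.0 CPM or more in the 3 microbead libraries and at 7578 CPM or less in all others, and Cx3cr1 and P2ry12 have their lowest group means in microbead.

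Microbead retinas were compared with naive retinas to ask how these microglia differ from those of uninjected eyes. C4b rose 125-fold, from 6.23 ± 4.12 (n = 4) to 776 ± 275 CPM (n = 3). The monocyte-attracting chemokines Ccl12 and Ccl2 rose from 145 ± 58.3 to 2270 ± 2111 CPM and from 63.3 ± 32.2 to 443 ± 119 CPM. Apoe rose from 5350 ± 1697 to 32510 ± 18400 CPM, the high-affinity IgG receptor gene Fcgr1 from 274 ± 30.5 to 788 ± 76.96 CPM, and Cd63 from 199.7 ± 3.14 to 792 ± 120.2 CPM. Sirpa, which encodes the receptor for the phagocytosis-inhibiting signal CD47, fell from 1624 ± 227 to 499 ± 210 CPM.

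In edgeR's quasi-likelihood test with the Benjamini-Hochberg correction, 30 of 14279 genes passed, 27 higher and 3 lower in microbead, and 1504 had an unadjusted p under 0.05. The largest rises at 10 CPM or more were C4b (chromosome 17, 34728380 to 34743882, minus strand) with a log2 fold change of 6.97 (SE 0.88, adjusted p = 0.00414) and Ccl12 (chromosome 11, 82101845 to 82103400, plus strand) with one of 3.97 (SE 0.57, adjusted p = 0.00986). Then came the interferon-induced Ifitm3 (2.84, SE 0.49), Ccl2 (2.81, SE 0.50), Cd72 (2.79, SE 0.41), Apoe (2.60, SE 0.43), Ifi30 (2.39, SE 0.37), the transcriptional regulator Id2 (2.38, SE 0.45), Rpl41, Cox4i1, Cox8a and the mitochondrial outer membrane protein gene Tspo (2.10, SE 0.41), with adjusted p between 0.00986 and 0.0426. The falls at 10 CPM or more were Sirpa (chromosome 2, 129592835 to 129632228, plus strand) with -1.70 (SE 0.29, adjusted p = 0.0269) and Ivns1abp with -1.33 (SE 0.26, adjusted p = 0.0415). Cd63 (1.99), the NF-kB inhibitor Nfkbia (1.60), Fcgr1 (1.52), the MHC class I gene H2-D1 (1.27) and Fth1 (1.26) were among the other genes that rose.

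The MGnD list had a median log2 fold change of 1.38 (camera adjusted p = 4.2e-10; adjusted p = 0.0191 with an estimated correlation). Adjusted over the list alone 12 of 31 genes rose, among them Cd63, Apoe, Ccl2, the cathepsin gene Ctsl (1.38), Gpnmb (6.36, SE 1.82) and Lgals3 (6.93, SE 2.20), against 5 over all genes tested. Cst7 had a log2 fold change of 2.85 (SE 1.18), Itgax 2.21 (SE 1.09), Csf1 1.82 (SE 1.44), Igf1 3.03 (SE 2.70), Spp1 2.49 (SE 2.49), Lpl -0.75 (SE 1.03), Clec7a -0.13 (SE 0.63), Axl 0.02 (SE 0.41) and Trem2 0.38 (SE 0.23), none of which passed. Antigen presentation had a median of 1.08 (adjusted p = 1.7e-08; adjusted p = 0.0310 with an estimated correlation), with 10 of 20 genes rising over the list alone. These included the MHC class II genes H2-Ab1 (184 ± 180 to 1492 ± 1216 CPM) and H2-Aa (87.8 ± 88.5 to 967 ± 676 CPM), their chaperone Cd74 and their regulator Ciita. Inflammatory genes had a median of 1.304 (adjusted p = 1.3e-08; adjusted p = 0.0191 with an estimated correlation), with 7 of 22 rising over the list alone, Ccl4 (2.18), Cxcl16 (1.49) and Tnf among them. After removal of the length trend these 3 medians were 1.17, 0.72 and 0.86, and each list passed.

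The interferon list had a median of 0.88 (adjusted p = 7.5e-06; adjusted p = 0.128 with an estimated correlation), phagocytosis and lysosome 0.43 (adjusted p = 9.3e-06; adjusted p = 0.1004 with an estimated correlation) and complement 0.37 (adjusted p = 0.00174; adjusted p = 0.1004 with an estimated correlation). Adjusted over the list alone, 2 of 28, 10 of 33 and 3 of 15 genes rose, the last being C4b, C1qb (0.82) and C1qa (0.60). Glycolysis and hypoxia genes had a median of 0.72 (adjusted p = 0.00993; adjusted p = 0.237 with an estimated correlation) with 0 of 21 passing edgeR's test over the list alone, where Aldoa, Pfkfb3, Gapdh and Eno1 had an unadjusted p under 0.05. Infiltrating monocyte and macrophage genes had a median of 2.54 (adjusted p = 0.00122; adjusted p = 0.235 with an estimated correlation), and 3 of 10 rose over the list alone: the matrix gene Fn1, at least 756-fold higher, S100a4 and Cd44 (4.14, SE 1.497). Microbead 2 and 3 carried this list, with mean scores of 3.255 and 3.933 from the naive mean, whereas microbead 1 scored -1.125, below every naive library, and sham 2 scored 3.173. Immediate early and heat shock genes, a sign of stress during cell isolation, had a median of 0.67 (adjusted p = 7.0e-04; adjusted p = 0.284 with an estimated correlation), with Hsp90ab1, Hsp90aa1 and Hspa8 as the 3 of 28 that rose over the list alone. Microbead libraries scored 0.222 to 0.6203 on it, naive 2 to 4 0.1266 to 0.2585 and the outlying naive 1 -0.58, and without naive 1 the median was 0.51 and the list passed. By mean log2 CPM per library, microbead and naive libraries overlapped for each of these 6 lists and for no other list that passed here. The length-corrected medians of these 6 lists were 0.58, 0.36, 0.36, 0.59, 2.35 and 0.62, and all passed.

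Ribosomal protein genes had a median of 1.398 (adjusted p = 4.8e-28; adjusted p = 0.0700 with an estimated correlation; 38 of 39 rose over the list alone), oxidative phosphorylation genes 1.07 (adjusted p = 1.3e-08; adjusted p = 0.00904 with an estimated correlation; 11 of 30) and mitochondrially encoded transcripts 0.98 (adjusted p = 1.5e-05; adjusted p = 0.190 with an estimated correlation; 3 of 13). Removal of the length trend brought them to 0.32, 0.10 and 0.24, again with a downward direction in camera, which ranks a list against other genes. The oxidative phosphorylation list then passed as lower (adjusted p = 0.00645). The homeostatic list did not pass camera (median -0.41, adjusted p = 0.138) but was lower by fry (adjusted p = 0.0321), and 8 of 28 genes fell over the list alone, with log2 fold changes of -0.96 for Serinc3, -0.76 for Cx3cr1 and -1.395 for P2ry12, and Ltc4s rose. Fry was not run with the length trend removed, and genes over 4000 bases had a median log2 fold change of -0.26 in this comparison. Tmem119 had -0.39 (SE 0.24), Sall1 -0.76 (SE 0.37), Itgam 0.16 (SE 0.27) and Fcrls 0.04 (SE 0.34). The replication helicase gene Mcm2, with 0 reads in the microbead libraries, was at least 112-fold lower, while the proliferation list as a whole did not pass (median -0.27, adjusted p = 0.805). TGF-beta signalling (-0.24, 0.793), lipid handling (median -0.02, mean 0.12, upward, 0.173), rod (0.43, 0.138), Muller glia and astrocyte (median -0.06, upward, 0.365), endothelial (-0.88, 0.648) and border-associated macrophage genes (median -1.03, upward, 0.805) did not pass. Nor did cone genes, whose median of -4.52 was -2.13 with genes at 0 set to their bound (upward, 0.805).

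The count of 30 genes depended on the naive libraries, with 1, 0, 5 and 1 genes passing without naive 1, 2, 3 and 4. It was 17, 52 and 168 without microbead 1, 2 and 3, and it was 2 with the length trend removed, C4b (7.10) and Cd72 (2.48). C4b also passed without every single library except naive 2 (adjusted p = 0.0619; 8.1e-35 to 0.0619 over 18 alternatives). The glycolysis list was lost without microbead 2 (adjusted p = 0.197) and the monocyte list without microbead 3 (0.0652). Over all alternatives the lowest adjusted p of the 12 lists lay between 1.6e-43 and 8.0e-04 and the highest between 0.00904 and 0.841, with the opposite call of oxidative phosphorylation included.

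**Figure D3:**
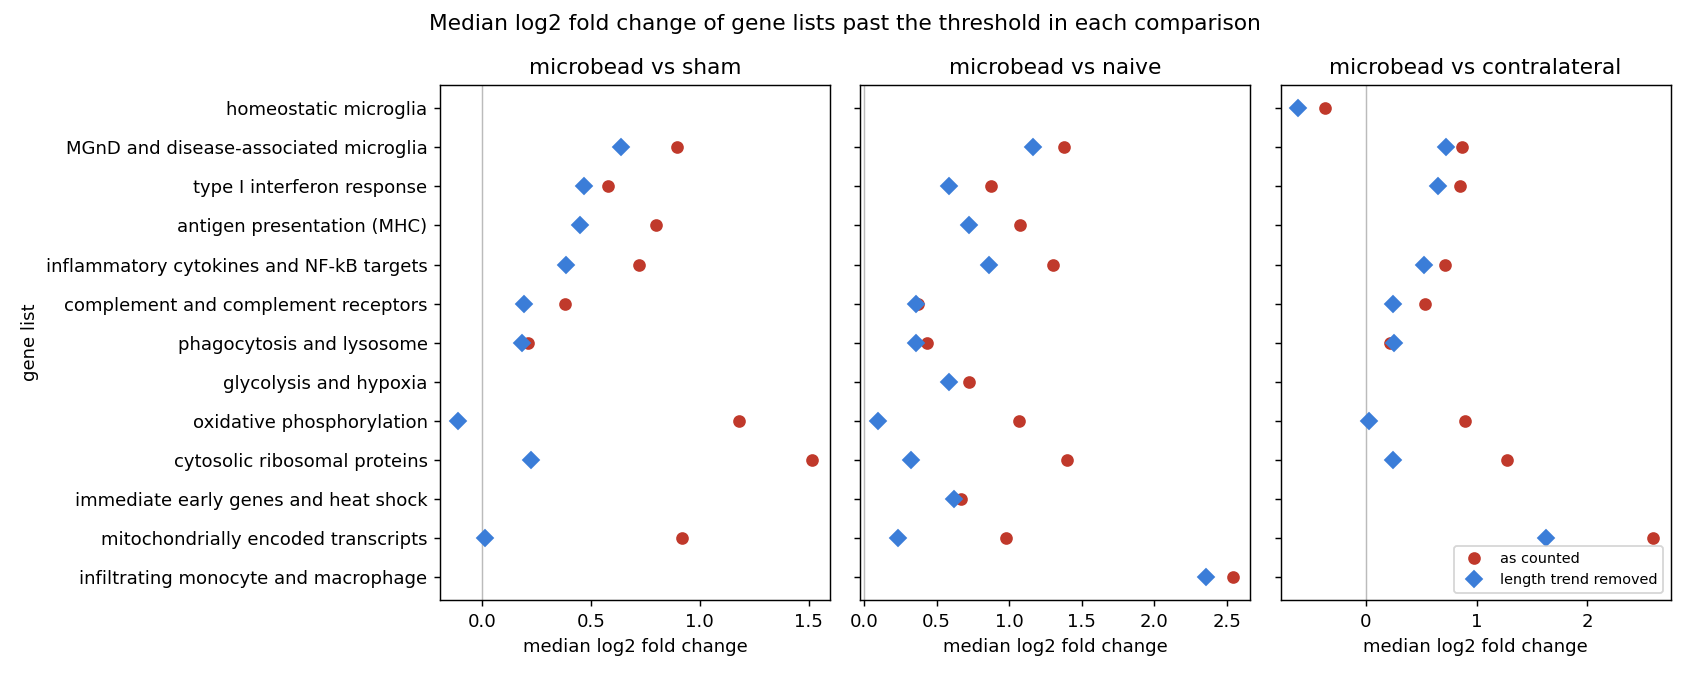
Median log2 fold change of the gene lists that passed in microbead against sham, naive and contralateral, as counted (red circles) and with the length trend removed from each library (blue diamonds). The medians of the ribosomal list against sham are 1.52 and 0.23, and those of the MGnD list 0.90 and 0.64.

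Microbead retinas were compared with contralateral retinas to ask how microglia differ between injected eyes and the other eyes. The labels do not say which of these retinas are the 2 eyes of 1 mouse, so they were compared as unpaired. Apoe again rose, from 4332 ± 3049 (n = 3) to 32510 ± 18400 CPM (n = 3). Mitochondrially encoded transcripts stood higher as a group in camera, a call lost with an estimated correlation (adjusted p = 0.0792). Of this group mt-Co2, a subunit gene of cytochrome c oxidase, rose from 97.48 ± 68.1 to 1553 ± 980 CPM, a 15.9-fold difference. Outside this list mt-Rnr2, the large mitochondrial ribosomal RNA, rose from 2201 ± 1131 to 10460 ± 4059 CPM. Stab1, a scavenger receptor gene of tissue macrophages, was at 181 ± 47.4 CPM in microbead against 712 ± 283 in contralateral. Its means of 369 ± 43.2 CPM in naive and 353 ± 39.4 in sham lay between them. The difference thus holds a high contralateral mean as well as a low microbead mean. The contralateral libraries had the lowest mitochondrial shares of reads, 0.164, 0.261 and 0.786%, against 0.871 to 2.12% in all others.

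In edgeR's quasi-likelihood test with the Benjamini-Hochberg correction 4 of 14279 genes passed, 3 higher and 1 lower in microbead, and 1649 had an unadjusted p under 0.05. They were mt-Co2 (mitochondrial genome, 7013 to 7696; log2 fold change 3.99, SE 0.53, adjusted p = 0.00756), mt-Rnr2 (1094 to 2675; 2.25, SE 0.36, adjusted p = 0.0358), Apoe (2.91, SE 0.49, adjusted p = 0.0400) and Stab1 (chromosome 14, 31139013 to 31168641; -1.98, SE 0.32, adjusted p = 0.0358). Next were Elmo1, an engulfment adaptor (-1.91, SE 0.34), C4b (4.58, SE 0.90) and Ccl12 (3.11, SE 0.62), each with an adjusted p of 0.0633.

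Mitochondrially encoded transcripts had a median of 2.59 (camera adjusted p = 6.1e-14; adjusted p = 0.0792 with an estimated correlation), and 11 of 13 rose over the list alone. Removing the length trend left a median of 1.63, and the list passed. The MGnD list had a median of 0.87 (adjusted p = 2.7e-06; adjusted p = 0.0796 with an estimated correlation), with 8 of 31 genes rising over the list alone, among them Cd52 (1.89), Gpnmb (8.23, SE 2.29) and the fatty acid carrier Fabp5, at least 767-fold higher than in contralateral, where it had 0 reads. Spp1 was at least 190-fold higher, from microbead 2 alone, and Itgax (2.67, SE 1.23), Lgals3 (6.17, SE 2.42), Cst7 (2.97, SE 1.32), Clec7a (0.81, SE 0.68), Lpl (1.10, SE 1.09), Igf1 (1.70, SE 2.87), Csf1 (0.12, SE 1.54), Axl (0.05, SE 0.44) and Trem2 (-0.18, SE 0.25) did not pass. The homeostatic list had a median of -0.37 (adjusted p = 0.0445; adjusted p = 0.468 with an estimated correlation), and 5 of 28 genes fell over the list alone: Slco2b1 (-1.14), Cx3cr1 (-1.08), Csf1r (-0.86), Selplg (-1.09) and Serinc3. P2ry12 (-1.08, SE 0.46), Tmem119 (-0.67, SE 0.26), Sall1 (-0.74, SE 0.39), Itgam (-0.24, SE 0.29) and Fcrls (0.51, SE 0.37) did not pass.

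The interferon list (median 0.85, adjusted p = 0.00107; adjusted p = 0.343 with an estimated correlation; 1 of 28 rose over the list alone), the inflammatory list (0.72, 0.00588; adjusted p = 0.309 with an estimated correlation; 4 of 22), complement (0.54, 0.0445; adjusted p = 0.343 with an estimated correlation; 1 of 15) and lysosome (0.22, 0.0445; adjusted p = 0.497 with an estimated correlation; 6 of 33) passed camera. The interleukin gene Il1b was one of the 4 inflammatory genes, at 94.9 ± 54.7 CPM against 2.39 ± 4.14. Ribosomal protein genes had a median of 1.28 (adjusted p = 6.1e-14; adjusted p = 0.309 with an estimated correlation; 29 of 39) and oxidative phosphorylation genes 0.89 (adjusted p = 1.9e-04; adjusted p = 0.0792 with an estimated correlation; 11 of 30). The length-corrected values of these 6 medians were 0.65, 0.52, 0.24, 0.26, 0.25 and 0.03, the last pair with a downward direction. The interferon, MGnD and mitochondrial lists then still passed as higher, the MGnD list with a median of 0.72, and the oxidative phosphorylation list passed as lower. Antigen presentation (0.75, adjusted p = 0.0745), rod (-0.52, 0.0699), endothelial (-2.14, 0.0745), monocyte (1.63, 0.0860) and border-associated macrophage genes (-1.98, 0.0699) did not pass.

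Without contralateral 2, 0 genes passed edgeR's test, and without microbead 1, 2 and 3 and contralateral 1 and 3 the counts were 7, 31, 162, 13 and 56. With the length trend removed, 1 gene passed, Stab1 (-1.95), and Apoe had a log2 fold change of 2.48. By mean log2 CPM per library, the groups overlapped for the homeostatic, interferon, complement and lysosome lists. Of 15 alternatives, the homeostatic list passed in 4 and the complement and lysosome lists in 6 each. Among the losses of the homeostatic list were fry (adjusted p = 0.0593), DESeq2's size factors (0.0666) and the length trend removed (0.0838). It was also lost without microbead 2 (adjusted p = 0.372), microbead 3 (0.0790), contralateral 2 (0.312) or contralateral 3 (0.0675), and the lysosome list without microbead 2 (0.0794), microbead 3 (0.135), contralateral 1 (0.131) or contralateral 3 (0.170). Complement was lost without microbead 2 (0.0794), microbead 3 (0.135), contralateral 1 (0.175) or contralateral 3 (0.0675), and the inflammatory list without contralateral 3 (0.0675). Over all alternatives the lowest adjusted p of the 9 lists lay between 1.8e-27 and 0.00563 and the highest between 0.0792 and 0.497, again with the opposite call of oxidative phosphorylation included.

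Sham-injected retinas were compared with naive retinas to measure the effect of the injection itself. No single gene passed edgeR's test (0 of 14279, with 380 at an unadjusted p under 0.05, 28 passing in DESeq2's Wald test and 0 in limma voom). Immediate early and heat shock genes were higher in sham as a group, with a median log2 fold change of 0.58 (camera adjusted p = 6.3e-07; adjusted p = 0.352 with an estimated correlation). Naive 1 stood apart on this list, at -0.58 from the naive mean against 0.13 to 0.26 in the other naive libraries, and without it the median was 0.43 and the list passed. Naive 1 was also the lowest naive library for the inflammatory, antigen presentation, glycolysis and border-associated macrophage lists below. Adjusted over the list alone, 5 of 28 rose: the chaperone genes Hspa8 (1286 ± 184 to 2387 ± 509.7 CPM, n = 4 each), Hspa1a (log2 fold change 2.44) and Dnajb1, and the transcription factor genes Egr2 (1.95) and Egr1 (0.67). Among single genes, C4b was at 43.2 ± 37.4 CPM in sham against 6.23 ± 4.12 in naive (2.80, SE 0.72, adjusted p = 1).

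Inflammatory genes had a median of 0.59 (adjusted p = 7.0e-06; adjusted p = 0.178 with an estimated correlation), with 19 of 22 higher in sham, among them Nfkbia (0.76), Tnf (1.26) and Ccl12 (1.57). Antigen presentation had a median of 0.28 (adjusted p = 9.6e-04; adjusted p = 0.352 with an estimated correlation), and H2-K1, a class I gene, was at 1420.0 ± 86.0 CPM against 926 ± 90. Border-associated macrophage genes, which mark perivascular and meningeal macrophages, had a median of 0.85 with 12 of 13 higher (adjusted p = 9.6e-04; adjusted p = 0.429 with an estimated correlation). The interferon (0.33, adjusted p = 0.0232; adjusted p = 0.573 with an estimated correlation), lysosome (0.19, adjusted p = 0.0335; adjusted p = 0.573 with an estimated correlation) and glycolysis lists (0.33, adjusted p = 0.0468; adjusted p = 0.573 with an estimated correlation) passed as well. In these 6 lists 0 genes passed edgeR's test over the list alone. The MGnD list (0.21, adjusted p = 0.131) and the homeostatic list (0.10, 0.578) did not pass.

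By mean log2 CPM per library, sham and naive libraries overlapped except for the lysosome and the immediate early and heat shock lists. Of 17 alternatives, the glycolysis list passed in 7 and the lysosome list in 9. The number of lists was 4 without naive 2, and 4 list calls needed particular libraries. Glycolysis was lost without sham 2 (adjusted p = 0.101), sham 3 (0.0790), sham 4 (0.169), naive 1 (0.189), naive 2 (0.0559) or naive 3 (0.0788), lysosome without sham 1 (0.0566), sham 3 (0.0790), sham 4 (0.0651), naive 1 (0.101) or naive 2 (0.0708), interferon without sham 2 (0.0843), sham 4 (0.184) or naive 2 (0.165), and border-associated macrophage genes without naive 1 (0.0846). Over all alternatives the lowest adjusted p of the 7 lists lay between 3.0e-09 and 0.00947 and the highest between 0.253 and 0.788.

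Contralateral retinas were compared with naive retinas to ask whether the uninjected eyes of injected animals differ from those of uninjected animals. Mitochondrially encoded transcripts were lower as a group in contralateral, with a median log2 fold change of -1.37 and all 13 lower (camera adjusted p = 3.0e-08; adjusted p = 0.286 with an estimated correlation). Contralateral 1 and 2 carried this, at mean scores of -3.02 and -2.12 from the naive mean, while contralateral 3 (-0.4857) was level with naive 4 (-0.4864). Adjusted over the list alone 6 fell, among them mt-Co2 (504 ± 110 to 97.48 ± 68.1 CPM; -2.37, SE 0.48) and mt-Nd1 (-1.51, SE 0.48). Immediate early and heat shock genes had a median of 0.69 (adjusted p = 1.8e-06; adjusted p = 0.377 with an estimated correlation), and Atf3, Hspa8, Hspa1a and Dnajb1 were the 4 of 28 that rose over the list alone. Contralateral 1 and 2 (1.249 and 0.8442) and the outlying naive 1 (-0.58) carried it, contralateral 3 (0.1345) lay within the other naive libraries, and without naive 1 the median was 0.49 and the list passed. No single gene passed edgeR's test over all genes (0 of 14279, with 740 at an unadjusted p under 0.05, 71 passing in DESeq2's Wald test and 0 in limma voom).

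Rod photoreceptor genes, which mark the most numerous neurons of the mouse retina, had a median of 0.62 with 19 of 25 higher in contralateral (adjusted p = 3.5e-05; adjusted p = 0.513 with an estimated correlation), Sag at 353 ± 114 CPM against 137 ± 108. Antigen presentation had a median of 0.55 (adjusted p = 6.0e-05; adjusted p = 0.286 with an estimated correlation) with 18 of 20 higher. The inflammatory list had a median of 0.46 (adjusted p = 0.0148; adjusted p = 0.497 with an estimated correlation), and the inflammasome gene Nlrp3 (198 ± 110 CPM against 59.0 ± 16.01) was the 1 of 22 that rose over the list alone. Border-associated macrophage genes had a median of 1.37 (adjusted p = 0.00835; adjusted p = 0.513 with an estimated correlation), with Stab1 (0.95) as the 1 of 13. The ribosomal (0.14, adjusted p = 0.0126; adjusted p = 0.622 with an estimated correlation) and lysosome lists (0.24, adjusted p = 0.0471; adjusted p = 0.513 with an estimated correlation) passed as well. The inflammatory, lysosome and ribosomal lists did not pass with the length trend removed (medians 0.39, 0.17 and 0.01), whereas the mitochondrial and rod lists did (-1.24 and 0.43).

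By mean log2 CPM per library, contralateral and naive libraries overlapped for each of the 8 lists. Of 16 alternatives, the lysosome list passed in 2, with fry (adjusted p = 0.792), DESeq2's size factors (0.0507) and no filter (0.149) among its losses, and the inflammatory and ribosomal lists in 8 each. Without contralateral 3, 11 genes passed, and 4 lists passed without naive 1. The ribosomal list was lost without contralateral 1 (adjusted p = 0.709), contralateral 2 (0.739), naive 2 (0.206) or naive 3 (0.207), the inflammatory list without contralateral 1 (0.107), contralateral 2 (0.0600) or naive 1 (0.142), the rod list without naive 1 (0.0778), border-associated macrophage genes without contralateral 3 (0.249) or naive 1 (0.107), and the lysosome list without any contralateral library (0.0945, 0.406 and 0.0953), naive 1 (0.156) or naive 2 (0.133). Over all alternatives the lowest adjusted p of the 8 lists lay between 2.8e-12 and 0.0349 and the highest between 0.286 and 0.906.

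Contralateral retinas were compared with sham-injected retinas, the remaining pair of control groups. Mitochondrially encoded transcripts were again lower as a group, with a median log2 fold change of -1.66 (camera adjusted p = 2.2e-10; adjusted p = 0.330 with an estimated correlation), and 8 of 13 fell adjusted over the list alone, mt-Co2 with -2.56 (SE 0.48). Contralateral 1 and 2 carried this fall too, and the median was -2.77 without contralateral 3. Rod photoreceptor genes had a median of 0.96 with 22 of 25 higher in contralateral (adjusted p = 2.1e-05; adjusted p = 0.834 with an estimated correlation). The rod arrestin gene Sag, at 353 ± 114 CPM against 67.3 ± 21.2 in sham (2.39, SE 0.61), was the 1 that rose over the list alone. No single gene passed edgeR's test over all genes (0 of 14279, with 694 at an unadjusted p under 0.05, 72 passing in DESeq2's Wald test and 0 in limma voom).

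Of 18 endothelial and pericyte genes 5 were measured, all higher, with a median of 2.38 (camera adjusted p = 0.00904, and 0.336 with an estimated correlation). Vitronectin, Vtn, was at 84.5 ± 35.4 CPM against 7.78 ± 5.35. Cldn5, Tek, Tie1, Ly6c1 and Rgs5, also genes of this list, had 0 reads in every library. Cone genes, of which 5 of 12 were measured, had a median of 4.58 (camera adjusted p = 0.0417, and 0.690 with an estimated correlation). The short-wave opsin gene Opn1sw, which had 0 reads in sham, was the 1 of 5 that rose over the list alone. Ribosomal protein genes had a median of 0.25 (adjusted p = 0.0134; adjusted p = 0.972 with an estimated correlation). The MGnD (-0.04, adjusted p = 0.883) and homeostatic lists (median 0.05, mean -0.03, 0.812) did not pass. With the length trend removed the cone and ribosomal lists did not pass (4.54 and 0.05), and the mitochondrial, rod and endothelial lists did.

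By mean log2 CPM per library, contralateral and sham libraries overlapped for the ribosomal, rod and cone lists. The cone list passed in 5 of 14 alternatives and the ribosomal list in 7 of 16. Without contralateral 3, 21 genes passed, and 2 lists passed without contralateral 1. The cone list was lost without contralateral 1 (adjusted p = 0.585), contralateral 3 (0.0778), sham 1 (0.0867) or sham 2 (0.0737), the ribosomal list without contralateral 1 (0.812), contralateral 2 (0.733) or sham 4 (0.0640), and the endothelial list without contralateral 1 (0.166). Over all alternatives the lowest adjusted p of the 5 lists lay between 1.6e-15 and 0.00390 and the highest between 0.330 and 0.972.

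Across all 4 groups at once, the genes that varied were those raised in microbead microglia. In edgeR's quasi-likelihood test of any difference, Benjamini-Hochberg adjusted, 32 of 14279 genes passed and 1167 had an unadjusted p under 0.05. Of the 32, 31 had their highest group mean in microbead, led by C4b (adjusted p = 0.00299), Apoe (0.00611), Cd72 (0.00887), Ccl12 (0.00973), mt-Co2 (0.0140) and Ifi30 (0.0191). The scavenger receptor gene Stab1 was the 1 with its lowest mean there. The count was 5 without microbead 1, 20 without microbead 2 and 79 without microbead 3. It was 87 and 94 without contralateral 1 and 3, 5, 7, 5 and 6 without sham 1, 2, 3 and 4, and 9, 6, 6 and 9 without naive 1, 2, 3 and 4.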

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

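No test in this part was chosen after its result was seen. In groups of 4 libraries, the gap between the highest or lowest library and its nearest neighbour was compared with the range of the group (Dixon's ratio), for depth, list scores and named genes of at least 10 CPM. Of 159 groups tested, 12 held an outlying library, and chance alone gives about 1 in 20. The groups of 3 libraries, microbead and contralateral, were not tested in this way.

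Sham 1 had 8.50 M reads, against 12.7 to 13.6 M in the other sham libraries. Its mitochondrial share of reads was 1.51%, against 1.00 to 1.09%. Its level of mt-Co2 was 812 CPM, against 472 to 517 CPM. Sham 2 had 40.2 CPM of Lgals3, against 0 in the other sham libraries. Fcer1g in sham 2 was at 769 CPM, against 884 to 899 CPM. Sham 4 had 101.5 CPM of Cd52, against 134 to 139.9 CPM. Lpl in sham 4 was at 49.95 CPM, against 21.9 to 24.7 CPM.

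Naive 1 had 97.49 CPM of Clec7a, against 191 to 205 CPM in the other naive libraries. The unnamed gene 2410006H16Rik in naive 1 was at 50.6 CPM, against 33.5 to 35.7 CPM. The mean log2 score of immediate early and heat shock genes, relative to the naive mean, was -0.58 in naive 1 and 0.13 to 0.26 in the others. The score of complement genes was 0.61 in naive 3 and -0.29 to -0.15 in the others. Fcgr1 in naive 4 was at 228 CPM, against 286 to 293 CPM.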

How the results depend on the processing

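Leaving out identifiers absent from the authors' table, leaving out libraries under 12000 genes and removing the length trend were chosen only after the data had been seen; the other alternatives were planned. Of the alternative values of named genes, 1186 kept their direction and side of the threshold, 300 fell short of it, 37 newly passed it and 44 reversed; of those of lists, 612 kept both, 173 fell short and 8 reversed. Except where stated the cause was not tested. Microbead 1 had 1.34 M reads, and what its depth limits was not tested, since leaving it out also leaves 2 libraries in its group. Counts of the series-wide table were not run because that table holds FPKM.

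Counts of genes past an adjusted p of 0.05 are given for microbead against sham, naive and contralateral in this order, where they were 2, 30 and 4. They were 139, 162 and 157 with no filter and 463, 576 and 664 with DESeq2's Wald test, whose calls against naive were 318 higher and 258 lower beside 27 and 3, those against sham 260 and 203 beside 2 and 0, and those against contralateral 330 and 334 beside 3 and 1. Limma voom gave 91, 194 and 2, the 2 compared groups alone 0, 5 and 0, and the rod covariate 0, 15 and 1, with fewer residual degrees of freedom in both of the last. Without the length trend they were 0, 2 and 1. DESeq2's size factors gave 46 against naive, and the filter at 50 reads 0 against sham and 2 against contralateral. Without the libraries under 12000 genes 7 passed against sham and 9 against contralateral. With the replicate number as a block, 1 passed against naive and 0 against contralateral, and neither Apoe nor Cd72 passed against sham. The same-numbered libraries correlated at -0.05 to 0.11 over 19 pairs, which gives no sign of a block shared by number. Among these, only pairs of microbead and contralateral retinas could be 2 eyes of 1 mouse. Their 3 pairs correlated at -0.04 to 0.09, which are too few to decide on a shared mouse. The labels leave open whether microbead and contralateral retinas of 1 number come from 1 mouse. Beside the 0 genes of the control comparisons, sham against naive, contralateral against naive and contralateral against sham, no filter gave 14, 21 and 22 and DESeq2's Wald test 28, 71 and 72. The 32 genes of the joint test became 54 with DESeq2's size factors, 314 with no filter, 478 with DESeq2's likelihood-ratio test, 82 with voom, 11 without the libraries under 12000 genes and 2 without the length trend.

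With each library left out in turn, the counts ranged from 0 to 134 against sham, 0 to 168 against naive, 0 to 162 against contralateral, 0 to 11 for contralateral against naive, 0 to 21 for contralateral against sham and 5 to 94 in the joint test. Lists ranged from 4 to 8 for sham against naive, 4 to 9 for contralateral against naive and 2 to 5 for contralateral against sham.

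Lists past the threshold, in the order of comparisons above, were 9, 12, 9, 7, 8 and 5, with an estimated correlation 1, 4, 0, 0, 0 and 0, and with fry 5, 7, 5, 0, 1 and 1. Those of fry include lower lists that camera did not call, homeostatic and TGF-beta signalling against sham and homeostatic against naive. Fry was not run with the length trend removed, so these lower calls were not tested against it. Removing the length trend left 5 lists for microbead against contralateral, 5 for contralateral against naive and 3 for contralateral against sham. The rod covariate left 4 and 3 for these control comparisons, the block 2 and the libraries over 12000 genes 3 for contralateral against sham. Without the length trend the camera direction reversed for oxidative phosphorylation, ribosomal and mitochondrial lists against sham (medians -0.11, 0.23 and 0.0151) and naive (0.10, 0.32 and 0.24), and for the first pair against contralateral (0.0332 and 0.25), and oxidative phosphorylation passed as lower in all 3 comparisons; the trend is what this setting removes.

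Reversed log2 fold changes against sham were Axl -0.0754 with the block, Trem2 -0.16 without the length trend and Igf1 -0.28 with the rod covariate. Against naive they were Fcrls -1.6e-05 with no filter, -0.0269 at 50 reads and -0.0923 with the block; Clec7a 0.0385 with voom and 0.21 without libraries under 12000 genes; Spp1 -0.53 with voom, -1.63 with the block and -0.83 with the rod covariate; Axl -0.0261 at 50 reads and -0.0898 with the rod covariate; and Trem2 -0.0324 without the length trend. Against contralateral they were Itgam 0.0437 and Trem2 0.17 without libraries under 12000 genes, Trem2 0.22 with voom, Axl -0.13 and Csf1 -0.39 with the block, and Igf1 -0.50 with the rod covariate. With libraries left out, the ranges against sham were Fcrls -0.11 to 0.42, Itgax -0.30 to 0.91, Axl -0.61 to 0.46, Lpl -0.17 to 0.56 and Igf1 -6.71 to 3.87. Against naive they were Itgam -0.0399 to 0.26, Fcrls -0.28 to 0.24, Clec7a -0.45 to 0.21, Spp1 -8.32 to 3.04, Axl -0.73 to 0.34 and Igf1 -6.81 to 9.77. Against contralateral they were Itgam -0.36 to 0.0167, Axl -0.64 to 0.43, Trem2 -0.44 to 0.0473, Csf1 -0.21 to 0.71 and Igf1 -7.98 to 4.78.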

Other observations

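The comparison of microbead with the mean of sham and naive, the removal of the length trend, the exclusion of libraries under 12000 genes, and the tests of microbead 1, of the contralateral level, of libraries with few genes, of Muller glia, of length for Apoe and C4b and of monocytes were chosen only after the results had been seen. The test of matched genes and the splits of the 183 genes and 10 lists below also rest on that added comparison. Against sham and naive combined, Cxcl13, a B-cell-attracting chemokine, rose from 0.20 ± 0.57 (n = 8) to 46.0 ± 29.0 CPM (n = 3), and Gpnmb from 1.43 ± 3.31 to 212 ± 267 CPM. Wfdc17 rose from 6.07 ± 9.27 to 107 ± 48.4 CPM and Cd300lf, a receptor for lipids of dying cells, from 13.3 ± 10.9 to 119 ± 16.7 CPM. Slc40a1, which encodes the iron exporter ferroportin, fell from 75.7 ± 12.6 to 13.5 ± 4.59 CPM while the ferritin chain Fth1 rose from 1769 ± 210.0 to 4005 ± 779 CPM. Hpgd, the enzyme that inactivates prostaglandins, fell from 290.1 ± 53.9 to 57.3 ± 34.1 CPM, Cmtm6 from 537 ± 174 to 96.1 ± 109 CPM and the Notch regulator Numb from 168 ± 29.1 to 55.0 ± 34.7 CPM.

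In edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted, 183 of 14279 genes passed, 160 higher and 23 lower in microbead, and 1709 had an unadjusted p under 0.05. The log2 fold changes were 5.57 for C4b (SE 0.62, adjusted p = 6.9e-04), 2.77 for Apoe (SE 0.35, adjusted p = 0.00115), 7.86 for Gpnmb (SE 1.45, adjusted p = 0.0127) and -2.50 for Slc40a1 (SE 0.51, adjusted p = 0.0204). Of the homeostatic genes, Cx3cr1 (-0.88, SE 0.20, adjusted p = 0.0345) and Serinc3 (-1.08, SE 0.24, adjusted p = 0.0318) fell. Without the libraries under 12000 genes 60 passed, without microbead 1, 2 and 3 there were 27, 161 and 285, and with the length trend removed 5 remained: C4b (5.70), Cd72 (2.37), Apoe (2.33), Rpsa (1.54) and Fcgr1 (1.26). Of 21 lists 10 passed camera, and the MGnD and oxidative phosphorylation lists also passed with an estimated correlation (adjusted p = 0.0296 and 0.00756).

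Other splits of the same libraries were tested for each count. For the genes of microbead against sham, 1 of 35 splits, the real one, gave as many (2, highest other 0). Against naive it was also 1 of 35 (30, highest other 1). For microbead against the mean of sham and naive it was 1 of 100 splits drawn (183, highest other 1). The joint test gave 1 of 100 as well (32, highest other 28). These shares are the smallest that so many splits can give. They argue against chance for these counts but do not exclude it. The count of 2 against sham fell to 0 when any single sham library was left out, and the highest other split of the joint test came close to the real one. For microbead against contralateral the splits are too few for a share under 0.05: 2 of 10 gave as many genes (4, highest other 18, a split that put microbead 1 with contralateral 1 and 2), and 1 of 10 gave as many lists (9, highest other 7). A split with several times the real count points to a structure of those libraries other than the groups. Chance cannot be excluded for the numbers of lists: 5 of 35 splits gave as many against sham (9, highest other 12), 4 of 35 against naive (12, highest other 13) and 23 of 100 against the mean of both (10, highest other 15). For sham against naive 2 of 35 gave as many lists (7, highest other 7), for contralateral against naive 2 of 35 (8, highest other 9) and for contralateral against sham 9 of 35 (5, highest other 6). With 0 genes in edgeR's test and highest others of 0, 3 and 0, all 35 splits reached the count in each control comparison, where 380, 740 and 694 genes had an unadjusted p under 0.05 and DESeq2 gave 28, 71 and 72.

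Ribosomal protein and oxidative phosphorylation genes stood higher in microbead libraries, with a pooled median log2 fold change of 1.299 over 69 genes against the mean of sham and naive. Genes outside both lists matched on length and expression had a median of 0.90, and 95% of 10000 matched lists had medians of 0.69 to 1.02, which is consistent with short transcripts being counted more in the microbead libraries as a source of most of the difference. The matched genes were longer than the list genes, with a median of 1100 against 704 bases, so the remainder may also follow from length. The shallow library microbead 1 is argued against as the cause, since the median without it was 1.00. What stays open is why length separates the groups, whether from RNA quality, library preparation or a change in the cells themselves after microbeads, which was not tested.

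Mitochondrially encoded transcripts were lower in contralateral than in microbead libraries, with a median of 2.59, and libraries with few detected genes are argued against as the cause, since the median without them was 1.85. Whether a low level in the contralateral libraries alone accounts for it cannot be told apart from a rise in microbead. With the length trend removed, the microbead libraries did not stand out from sham and naive (difference -0.08, exact two-sided permutation p = 0.848), whereas as counted they stood 0.93 higher (exact permutation p = 0.00606). The mean of the contralateral libraries lay below that of sham and naive both as counted (-2.00, exact permutation p = 0.0121) and with the trend removed (-2.12, exact permutation p = 0.0121), over 165 splits. As counted, contralateral 1 and 2 carried this (-3.02 and -2.12 from the naive mean), while contralateral 3 (-0.4857) was level with naive 4 (-0.4864).

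Apoe and C4b were higher in microbead libraries, and both are also made by other cells of the retina. RNA from Muller glia and astrocytes is argued against for Apoe, which gained 27700.0 CPM. The other 9 measured genes of that list gained 17.0 CPM in sum (380 ± 71.0 against 363 ± 29.8). For C4b, at 776 ± 275 CPM in the microbead libraries, this source was not tested and stays open. Short transcripts being counted more is argued against as the whole cause, since with the length trend removed the log2 fold changes were 2.33 for Apoe (SE 0.39, adjusted p = 0.0476) and 5.70 for C4b (SE 0.63, adjusted p = 6.4e-04). Those values are from the added comparison with the mean of sham and naive. With the trend removed, Apoe passed edgeR's test in none of the planned microbead comparisons, and C4b passed against naive alone. Infiltrating monocytes and macrophages cannot be told apart from a change in microglia. Their list stood 1.55 higher, with a spread between libraries that left an exact two-sided permutation p of 0.236. From the naive mean, microbead 2 and 3 scored 3.255 and 3.933 on it, microbead 1 -1.125 and sham 2 3.173. The sort on Fcrls and against Ly6c was meant to remove such cells, and whether it removed all of them was not tested. The level of Fn1, 49.9 ± 56.6 CPM, does not give their share. A response of the microglia themselves to microbeads stays open as well and was not tested.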
